A study of Rattus norvegicus with 6 samples.

How the data were processed

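Hippocampus of Sprague-Dawley rats was flash frozen, and RNA or DNA was extracted for RNA-seq, miRNA-seq and RRBS libraries, per the labels' protocols. The 6 libraries were grouped by their titles as B[a]P or control for each of the 3 assays, with 1 library per group. The labels do not say whether the 3 assays used the same animals or pooled tissue. The submitters' processing notes name bcl2fastq and the genome builds rn6 and rn5, with no role for each. The aligner, the counting tool, the methylation caller and the annotation were not given in the sources used here.

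The mRNA and lncRNA tables hold FPKM values as deposited, with 1 value per line and library. No label states their unit. It was inferred from the values: the sums exceed those of a per-million scale, and for 3935 symbols under 0.05 FPKM the ratio of the libraries lay on ratios of whole numbers up to 6 times 1 constant for 73.0% of symbols, within 0.001 on the natural log scale, against 0.0508% at shifted constants. That constant gave the relative depth of 1.06, control over B[a]P. Whether reads or fragments were counted, and the total, were not given, so no counting interval was computed for FPKM values. All 13143 symbols of the lncRNA table are also in the mRNA table. For symbols on 1 line its values were 0.474 times those of the mRNA table in the B[a]P library and 0.497 times in the control library, within 0.1% for 92.2% and 92.1% of symbols, so it carries another scaling of the same measurements for most of them. Of the 35362 symbols, 19187 (54.3%) matched the symbols of the RefSeq gene table of assembly GRCr8, which was used for names only. Reads shared between near-identical copies of a gene could be split by the authors' counting, and this affects histone, ribosomal protein and major histocompatibility genes. The highest value in the table, of LOC102723236, was 1070000 FPKM in the B[a]P library and 1240000 FPKM in the control library.

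The miRNA tables hold RPM values as deposited for 765 mature miRNAs. All values above 0 were whole multiples of 1 step per library, within 0.01, and the smallest was 10 steps, so values under 10 reads would be listed as 0. A 0 need not mean few reads. let-7a-5p and miR-125b-5p were at 0 in both libraries, while let-7f-5p had 209499 (B[a]P) and 185207 (control) reads and miR-125b-2-3p 5858 and 5480. The reason was not given, and let-7a-5p is missing from the let-7 list's median. The steps gave totals of 14.4 M (B[a]P) and 16.3 M (control) reads, of which miRNAs took 46.9% and 37.1%. Numbers of reads were computed from these steps. Ratios of 2 read numbers have exact conditional binomial 95% intervals.

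The RRBS tables give the counts of methylated and unmethylated reads of each cytosine and its methylation level in percent, per the file headers. A status letter gives the context (CpG, CHG or CHH), and no column gives the strand. Every deposited site had 10 reads or more, so the authors' filter sets the lowest coverage. Positions on chromosome 1 reached 290084085, past the end of that chromosome in rn6, so positions are given as rn5, as printed in the files' start column, whose base (counted from 0 or 1) is not known. A low coverage limit, duplicate removal and the treatment of filled-in fragment ends could each change a level, and were not given.

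For expression, the ratio of the B[a]P to the control library was computed as log2(value + pseudocount), with a pseudocount of 1 for mRNA and miRNA values and 0.1 for lncRNA values, which understates the ratio of low genes. Folds printed for single genes are ratios of the values without pseudocount. Features at 1 FPKM (mRNA), 0.5 FPKM (lncRNA) or 10 RPM (miRNA) in either library were kept. A feature passed the size rule at an absolute log2 ratio of 1, and no p-value was computed. Of the lists fixed before the data were examined, 40 hold mRNAs, 11 miRNAs and 1 lncRNAs. Members were matched on symbol or name, each miRNA arm on its own. A list with 3 or more members above the floor has a median and its percentile among 10000 random lists matched in 20 bins of mean level. Tested on simulated shifts in the real mRNA table, with 100 lists of 15 genes for each, a shift of 0.2 placed 99% of lists outside the central 95%, a shift of 0.5 placed 100%, and no shift placed 7%. These genes were drawn at random, so the test does not cover lists of related genes.

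For methylation, 5628789 cytosines present in both libraries were joined by position, after 422 whose context differed were left out. A 2-sided Fisher's exact test was run at each of 1215420 CpG sites with the Benjamini-Hochberg adjustment, and sites were called at an adjusted p under 0.05 and 25 percentage points. A site is a single cytosine, so the strands of a CpG count as separate sites. Both strands were present for 289570 CpGs. Tiles of 1000 bp with 5 or more sites were called at an adjusted p under 0.05 and 10 points, from summed reads. Tiles replace the planned promoters because no annotation of the files' build was at hand. The planned comparison of promoter methylation with expression was not run for the same reason. The median coverage of tested sites was 57 reads in the B[a]P library and 74 in the control library. On simulated reads at the real coverages, with 100 sites changed by 30 points and 100 by 50 points among 1215420, the test recovered 13 and 60, all 73 in the right direction, and called 0 unchanged sites. Single sites at ordinary coverage were therefore often missed in the simulation. In the real data 2355 sites had an adjusted p under 0.05, which makes the adjusted threshold less strict, so these recoveries need not hold there. Sequencing reads without molecular identifiers are not independent molecules, so intervals and tests cover counting error only.

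Genes to be named were set by a rule before the data were examined: the 2 to 4 members of each list with the largest absolute log2 ratio above the floor, the most abundant member of a cell type list, the aryl hydrocarbon receptor genes and DNA methylation enzymes whatever their values, the 10 largest ratios each way with a symbol, 5 lncRNAs each way, 6 miRNAs each way and the 5 most abundant, 6 tiles each way by size, and 3 CpG sites each way by adjusted p. Other genes and miRNAs named, such as further list members and those of the closing section, were chosen after their values were seen. Alternatives changed the scaling, the pseudocount, the floor, the summary of a list, the coverage minimum, the deepest 0.1% of sites, the size of the difference, the depth, the tile size and the weighting of sites, 1 at a time. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots matplotlib 3.10.9.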

Results

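The series examined the hippocampus of Sprague-Dawley rats given benzo[a]pyrene (B[a]P), a polycyclic aromatic hydrocarbon formed by incomplete combustion that activates the aryl hydrocarbon receptor and whose metabolites bind DNA. B[a]P in corn oil was given by daily oral gavage at 2.0 mg/kg, and the control received the corn oil alone. The labels gave 7 weeks of gavage for the RNA-seq libraries and an age of 7 weeks for all 6 libraries. They do not say whether that age is at the start or the end of gavage, so the age at sampling is in doubt. Each condition had 1 RNA-seq library, 1 small RNA (miRNA-seq) library and 1 reduced representation bisulfite sequencing (RRBS) library, a method that reads cytosine methylation in CpG-rich fragments. No difference below has a replicate check, and every value compares 2 libraries, not the conditions. The mRNA table listed 35362 symbols, and the steps of low values gave the control library 1.06 times the depth of the B[a]P library. No label gave the unit of the mRNA and lncRNA tables, which was taken as FPKM from the values, nor a total number of reads. The miRNA tables corresponded to totals of 14.4 M and 16.3 M reads in the B[a]P and control libraries, of which 6737677 and 6039463 were assigned to miRNAs. The RRBS tables held 1441423 CpG sites in the B[a]P library, at a median of 47 reads, and 1251142 in the control library, at a median of 72 reads.

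The comparison of the RNA-seq libraries asked which hippocampal transcripts differed after B[a]P. Among genes lower in the B[a]P library, the largest differences were in transcripts of the choroid plexus, the epithelium that secretes cerebrospinal fluid. Ttr, which encodes the thyroid hormone carrier transthyretin, was at 60.5 FPKM in the B[a]P library and 3300.2 FPKM in the control library, 54.6-fold lower. Kl, which encodes klotho, was 31.8-fold lower (0.724 against 23.1 FPKM). The folate receptor gene Folr1 was 24.4-fold lower, the chloride channel gene Clic6 22.6-fold lower, and the water channel gene Aqp1 26.4-fold lower. The tight junction gene Cldn2 (0.403 against 12.3 FPKM), Tmem72 (0.224 against 8.97 FPKM) and Mfrp (0.362 against 8.83 FPKM) were lower as well. Igfbp2, an insulin-like growth factor binding protein gene, was 7.41-fold lower, and Enpp2, which encodes the lysophospholipase autotaxin, 6.67-fold lower (15.04 against 100.2 FPKM). These were the 10 lowest log2 ratios with a gene symbol.

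Over the 13261 genes at 1 FPKM or more in either library, 20 were at least 2-fold higher and 69 at least 2-fold lower in the B[a]P library, on the scale of log2(FPKM + 1). The choroid plexus and ependymal list, of only 17 genes, held 10 of those 69 genes and the endothelial, pericyte and meningeal list held 2. The tissue source of the remaining lower genes was not assessed, so 10 is not the full number of choroid plexus genes among them. At 1.5-fold, 80 genes were higher and 157 lower, and 98.2% of genes lay within 1.5-fold. The median log2 ratio was 0.09 (SD 0.25 across genes). The counts depended on how low values were treated: with a pseudocount of 0.1 they were 53 and 127, and with a floor of 5 FPKM 11 and 36.

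The 10 highest log2 ratios with a gene symbol were mostly of low-level genes, tRNAs and histone genes. Trny, which by its symbol is the mitochondrial tyrosine tRNA, was at 867 FPKM in the B[a]P library and 4.57 FPKM in the control library. Ndufa10l1, a paralogue of a complex I subunit gene, was at 6.39 against 0.0300 FPKM. The histone genes H3f3c (7.01 against 0.185 FPKM) and Hist2h2ac (22.2 against 6.27 FPKM) have near-identical relatives, and their values are uncertain where reads are shared. Tph1, which encodes the tryptophan hydroxylase of non-neuronal tissues, was at 1.14 against 0.0179 FPKM. Ifit3, an interferon-induced gene, was 2.82-fold higher (7.74 against 2.74 FPKM). Ghdc (3.24 against 0.728 FPKM), Otop3 (1.48 against 0.160 FPKM), the serine tRNA Trns2 (7.41 against 3.05 FPKM) and the class I major histocompatibility gene RT1-M6-2 (3.60 against 1.29 FPKM) completed them. Predicted genes without an established symbol made up 10 of the 20 genes at least 2-fold higher, against 13.8% of all genes above the floor.

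Lists of genes fixed before the data were examined showed which groups stood apart. For each, the median log2 ratio was set against 10000 random lists of the same size and expression level, which describes these libraries and is no test of the treatment. Of 38 mRNA lists with a median, 11 lay above and 11 below the central 95% of their random lists. If the lists were themselves random draws of genes, 1.9 in all would be expected. Related genes can vary together between any pair of samples, so 1.9 is not the chance number for lists such as these. Random lists followed the overall median, so a list could lie low with a median near 0.

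**Figure D1:**
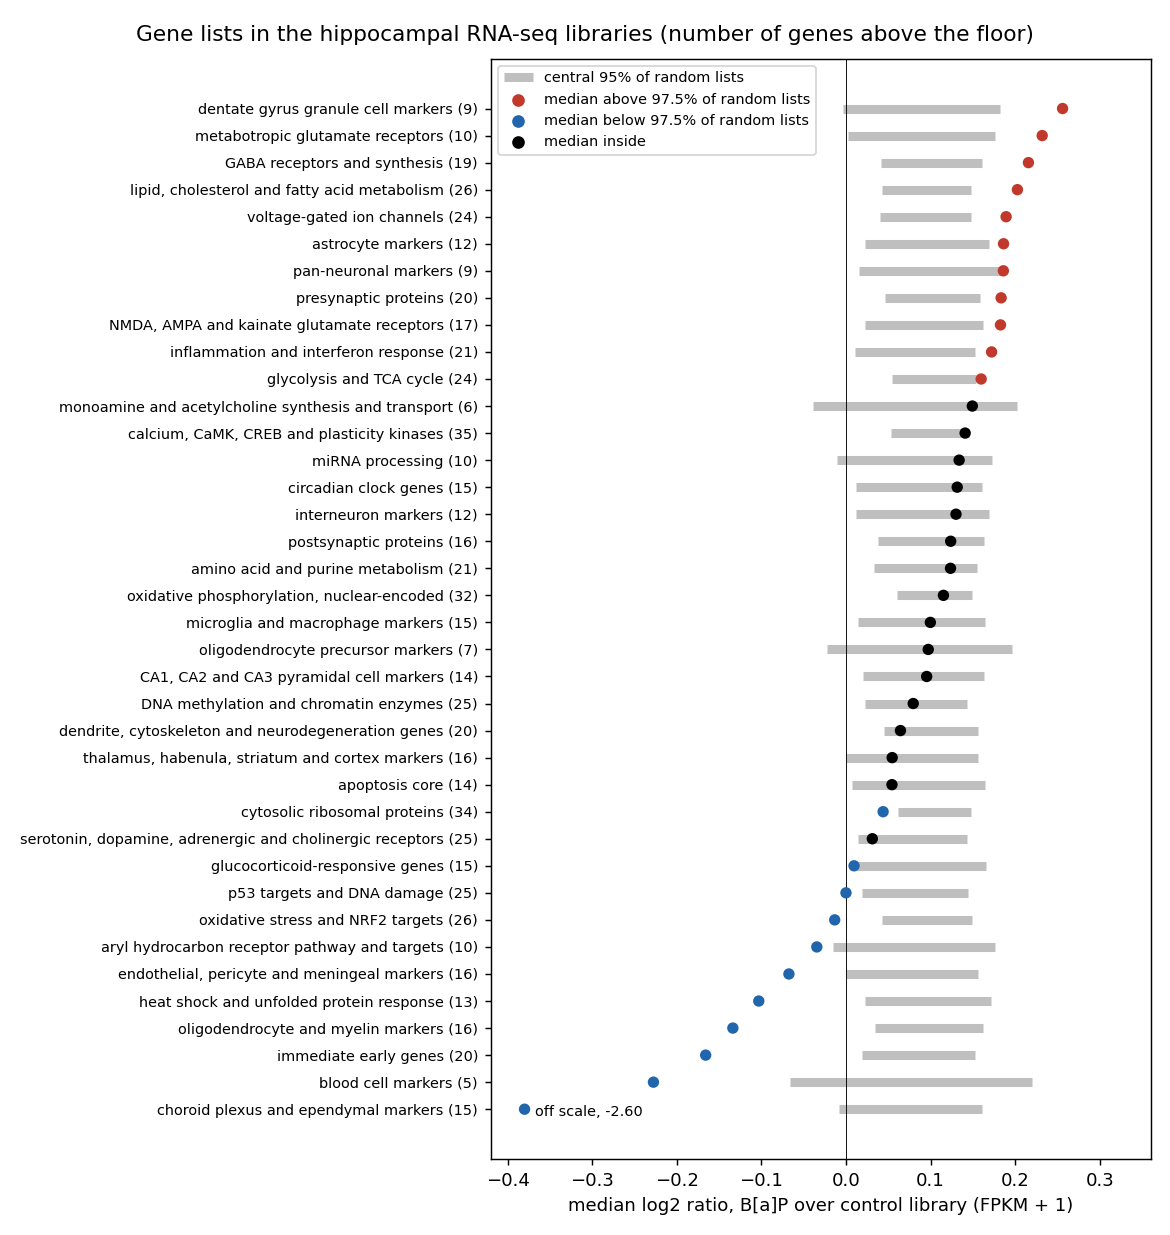
Median log2 ratio of each mRNA list, B[a]P over control library (x axis), with the number of genes above the floor after each name. Grey bars give the central 95% of random lists, and the choroid plexus and ependymal list lies off the scale at -2.60.

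The genes that answer the aryl hydrocarbon receptor, the receptor for B[a]P, did not stand out upward. Cyp1a1, the receptor's classical target and a B[a]P-oxidising enzyme, was at 0.0261 FPKM in the B[a]P library and 0.0329 FPKM in the control library, and Cyp1a2 was listed at 0 in both. Cyp1b1 was at 1.73 against 1.20 FPKM, Ahr at 1.99 against 1.74 FPKM, its partner Arnt at 3.73 against 3.40 FPKM, and the repressor Ahrr at 0.0364 against 0.0596 FPKM. None of the 10 list members above the floor differed by 1.5-fold, and their median was -0.03 (percentile 1.17). Among other members, Ugt1a6, which encodes a conjugating enzyme, was at 1.45 against 1.94 FPKM and Nqo1, a quinone reductase gene, at 6.42 against 7.41 FPKM.

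Stress response lists lay low. The oxidative stress and NRF2 list had a median of -0.01 (percentile 0.01), with 18 of 26 genes below the table's median. Gsta4, a glutathione transferase gene, was at 11.9 against 21.5 FPKM, Mt1a, a metallothionein gene, at 14.9 against 23.1 FPKM and the glutathione peroxidase gene Gpx1 at 39.2 against 57.5 FPKM. The p53 target and DNA damage list had a percentile of 0.54, with 19 of 25 genes below the table's median. Its largest differences were Pmaip1, which encodes the apoptosis mediator Noxa (1.11 against 2.13 FPKM), and the cell cycle inhibitor gene Cdkn1a (5.04 against 7.36 FPKM). All 13 heat shock and unfolded protein genes above the floor lay below the table's median (list median -0.10), led by the small heat shock protein gene Hspb1 (3.05 against 8.39 FPKM) and by Hspa5, the chaperone gene of the endoplasmic reticulum (146 against 192 FPKM). The glucocorticoid-responsive list (median 0.01, percentile 2.06) held Lcn2 at 0.587 against 1.21 FPKM and Zbtb16 at 20.6 against 15.01 FPKM. The apoptosis core list (median 0.05, percentile 19.1) lay inside the random range.

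Immediate early genes, which neuronal activity induces within minutes, were lower as a group. Their median log2 ratio was -0.17, below all 10000 random lists, and 18 of 20 lay below the table's median. Arc was at 20.8 against 36.5 FPKM, Fos at 4.08 against 6.60 FPKM, Egr1 at 4.83 against 7.37 FPKM and Nr4a1 at 2.06 against 3.27 FPKM. None reached 2-fold.

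Several receptor and synaptic lists lay high, each by a small amount. Pan-neuronal and astrocyte markers, described below, had medians of 0.19 each, so shifts of this size were not particular to receptor or synaptic genes. The metabotropic glutamate receptor list had a median of 0.23 (percentile 99.94), led by Grm2 at 7.48 against 4.26 FPKM and Grm3 at 22.1 against 17.2 FPKM. GABA receptor and synthesis genes had a median of 0.22, with 17 of 19 above the table's median, among them Gabra2 (49.4 against 38.8 FPKM) and Gabbr2 (36.7 against 28.9 FPKM). The ionotropic glutamate receptor list had a median of 0.18 (percentile 99.7), with Grik1 at 2.92 against 2.21 FPKM and Gria2 at 112 against 95.5 FPKM. Presynaptic protein genes had a median of 0.18, with the SNARE gene Snap25 at 306 against 250.1 FPKM and Nrxn3 at 18.5 against 15.1 FPKM. Voltage-gated ion channel genes had a median of 0.19, with Cacna2d1 at 29.8 against 23.8 FPKM. The calcium and plasticity kinase list (0.14, percentile 96.2) and the postsynaptic list (0.12, percentile 75.2) lay inside the random range. So did the monoamine and acetylcholine receptor list (0.03, percentile 6.67), in which the serotonin receptor gene Htr2c was at 19.5 against 29.0 FPKM. No member of these lists reached 2-fold.

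Markers of cell types lay on both sides. Pan-neuronal markers had a median of 0.19 (percentile 97.9), with Map2 at 151 against 111 FPKM and Uchl1, the most abundant, at 429 against 383 FPKM. Dentate granule cell markers had a median of 0.26 (percentile 99.95), with Sema5a at 17.5 against 13.2 FPKM, Prox1 at 10.5 against 8.15 FPKM and Calb1 at 43.9 against 36.6 FPKM. Astrocyte markers had a median of 0.19 (percentile 99.4), with the glutamate transporter gene Slc1a2 at 291 against 219 FPKM and the filament gene Gfap at 224 against 172 FPKM. Oligodendrocyte and myelin markers were lower, with a median of -0.13 and 14 of 16 below the table's median. Mal was at 105 against 144 FPKM, the lineage factor gene Olig2 at 7.80 against 10.3 FPKM and Mbp, the most abundant, at 733 against 861 FPKM. All 16 endothelial, pericyte and meningeal markers lay below the table's median (list median -0.07), led by Slc13a4 (2.43 against 11.3 FPKM) and Igf2 (3.37 against 13.8 FPKM). Blood cell markers had a median of -0.23 over 5 genes, with the globin gene Hbb at 140.2 against 177 FPKM. Markers of microglia (0.10), interneurons (0.13), oligodendrocyte precursors (0.10), pyramidal cells (0.10) and neighbouring brain regions (0.05) lay inside their random ranges.

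The choroid plexus and ependymal list had a median of -2.60, and 10 of its 15 genes above the floor were at least 2-fold lower. The ratio of those 10 between the libraries ranged from 6.67 to 54.6, with a median of 25.3. Ependymal cilia genes of the list differed less: Foxj1 was at 1.94 against 4.77 FPKM, Rsph1 at 1.06 against 2.10 FPKM and Dynlrb2 at 3.53 against 5.07 FPKM.

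Inflammation and interferon response genes had a median of 0.17 (percentile 99.3). After Ifit3, its relative Ifit2 was at 4.99 against 2.18 FPKM, the acute phase gene Serpina3n at 2.07 against 0.670 FPKM and the antiviral gene Mx1 at 5.16 against 2.42 FPKM. Metabolic lists were also high, with medians of 0.20 for lipid and cholesterol genes (24 of 26 above the table's median; Lss, of sterol synthesis, at 5.39 against 3.54 FPKM) and 0.16 for glycolysis and the citric acid cycle (Pgk1 at 169 against 121 FPKM and Ogdh at 9.25 against 6.23 FPKM). Cytosolic ribosomal protein genes had a median of 0.04 (percentile 0.26). Rpl30 (71.6 against 156 FPKM) and Rps6 (1.12 against 4.53 FPKM) were over 2-fold lower, and both have many processed copies in mammalian genomes. Nuclear genes of oxidative phosphorylation lay inside the random range (0.12), although Cox5b was at 274 against 147 FPKM. The same held for the lists of circadian clock genes (0.13), dendrite and neurodegeneration genes (0.06), monoamine and acetylcholine synthesis (0.15) and miRNA processing (0.13), and for amino acid and purine metabolism (0.12), where the serine synthesis gene Phgdh was at 24.0 against 38.2 FPKM. The sex-linked list had no gene above the floor, and no member of the list of 13 mitochondrially encoded protein genes was matched.

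Genes of DNA methylation differed little. The maintenance methyltransferase gene Dnmt1 was at 4.55 against 4.08 FPKM, the de novo methyltransferase genes Dnmt3a at 6.33 against 5.93 FPKM and Dnmt3b at 0.127 against 0.109 FPKM. Among the genes of 5-methylcytosine oxidation, Tet1 was at 2.14 against 1.77 FPKM, Tet2 at 4.19 against 3.34 FPKM and Tet3 at 2.53 against 2.47 FPKM. Tdg, a base excision glycosylase gene, was highest relative to the control library at 12.3 against 8.87 FPKM. The list's median of 0.08 had a percentile of 42.7.

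In the long noncoding RNA table, the largest differences were again of tRNA and predicted genes. Of 2007 lines at 0.5 FPKM or more in either library, 21 lines (16 symbols) were at least 2-fold higher and 18 lines (14 symbols) at least 2-fold lower in the B[a]P library. The tRNA Trny (411 against 2.27 FPKM) was highest, followed by LOC103692946 (2.43 against 0.0758 FPKM), LOC100363537 (7.39 against 0.498 FPKM), the tRNA Trnl2 (0.609 against 0.0753 FPKM) and LOC102547853 (1.08 against 0.228 FPKM). LOC102549864 was lowest (0.140 against 2.33 FPKM), with 3 lines of LOC100912617 (the first at 0.0655 against 1.495 FPKM) and LOC103694382 (0.111 against 1.22 FPKM). Of 36 brain lncRNAs listed in advance, 7 were found. Miat, a nuclear RNA of neurons, was at 13.4 against 11.2 FPKM, Snhg11 at 14.6 against 12.8 FPKM, Snhg4 at 2.65 against 2.73 FPKM, Gas5 at 18.1 against 18.5 FPKM, the dendritic RNA Bc1 at 1.38 against 1.78 FPKM, Rmrp at 15573 against 18613 FPKM, and H19 at 0.0675 against 0.133 FPKM, below the floor. Scaling each library to its median moved the median log2 ratio by -0.17 and turned the split from 21 higher and 18 lower to 14 higher and 19 lower.

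The miRNA-seq libraries were compared to find miRNAs that differed after B[a]P. Here the miRNAs of the choroid plexus were higher in the B[a]P library, the opposite of the choroid plexus mRNAs. miR-204-5p, an abundant choroid plexus miRNA, was 6.90-fold higher (42386 against 6959 reads; 95% interval 6.73 to 7.08). miR-1298 was 18.6-fold higher (52618 against 3198 reads; 95% interval 18.0 to 19.3), miR-448-3p 19.2-fold higher (3453 against 204 reads) and miR-1912-3p 25.3-fold higher (268 against 12 reads; 95% interval 14.2 to 49.6). These last 3 lie within introns of the serotonin receptor gene Htr2c, which is strongly expressed in choroid plexus. miR-34b-5p was 6.12-fold higher (562 against 104 reads), and miR-34c-5p, from the same precursor transcript and abundant in ciliated and choroid epithelium, 4.18-fold higher (28429 against 7698 reads). The intervals are exact and cover counting error only.

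Of 332 miRNAs at 10 RPM (reads scaled to the library total) or more in either library, 13 were at least 2-fold higher and 0 at least 2-fold lower in the B[a]P library. Values were higher across the table, with a median log2 ratio of 0.36, and scaling by the median of ratios moved it by -0.36. Relative to the table's median, the log2 ratio was 3.85 for miR-1298, 2.42 for miR-204-5p and 1.70 for miR-34c-5p. The other miRNAs past the size rule were miR-204-3p (6.76-fold), miR-34c-3p (4.72-fold), miR-34b-3p (3.998-fold), miR-200a-3p (4.24-fold), miR-375-3p (3.25-fold), miR-219a-5p (2.20-fold) and miR-152-3p (2.16-fold). The last 2, at 0.77 and 0.74 relative to the table's median, fell short of the size rule once the shift was removed, which left 11. The lowest ratio was that of miR-3553, 2.13-fold lower in RPM (107 against 258 reads) and -1.36 on the log2 scale relative to the table's median. The liver miRNA miR-122-5p (114 against 201 reads), miR-205 (125 against 170 reads), the erythroid miR-451-5p (577 against 772 reads), miR-129-2-3p (4542 against 5392 reads) and miR-1843a-3p (424 against 504 reads) followed. By the deposited values, in which some miRNAs such as let-7a-5p are at 0, the 5 most abundant differed by 1.35-fold or less: the neural miR-9a-5p (1374102 against 1354388 reads), miR-128-3p (448525 against 392228 reads), miR-7a-5p (313269 against 314841 reads), miR-26a-5p (279880 against 235506 reads) and miR-99a-5p (272938 against 234418 reads).

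Of the 10 miRNA lists with a median, 3 lay above and 1 below the central 95% of their random lists. The choroid plexus and ependymal list had a median log2 ratio of 2.06, with 7 of 7 members above the floor at least 2-fold higher. These members were both arms of miR-204, miR-34b and miR-34c, and miR-200a-3p, so they are not independent. Apart from miR-204-5p and miR-34c-5p, they reached the floor of 10 RPM in the B[a]P library only, which favours higher ratios. The p53-associated list (median 0.52) held the 4 miR-34b and miR-34c arms and miR-34a-5p, the third family member, at 822 against 644 reads. The oligodendrocyte-enriched list (median 0.56) held miR-219a-5p (2904 against 1494 reads) and miR-338-5p (6269 against 4045 reads). Neuronal and plasticity miRNAs were lower than random lists at a median of 0.26, with miR-124-3p at 33856 against 30565 reads and miR-132-3p at 6907 against 6150 reads. The let-7 (0.36), blood-enriched (0.27), inflammation-associated (0.29), endothelial (0.46), miR-17-92 (0.45) and sensory and epithelial cluster (0.55) lists lay inside their random ranges. The muscle and liver list had 2 members above the floor and no median.

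**Figure D2:**
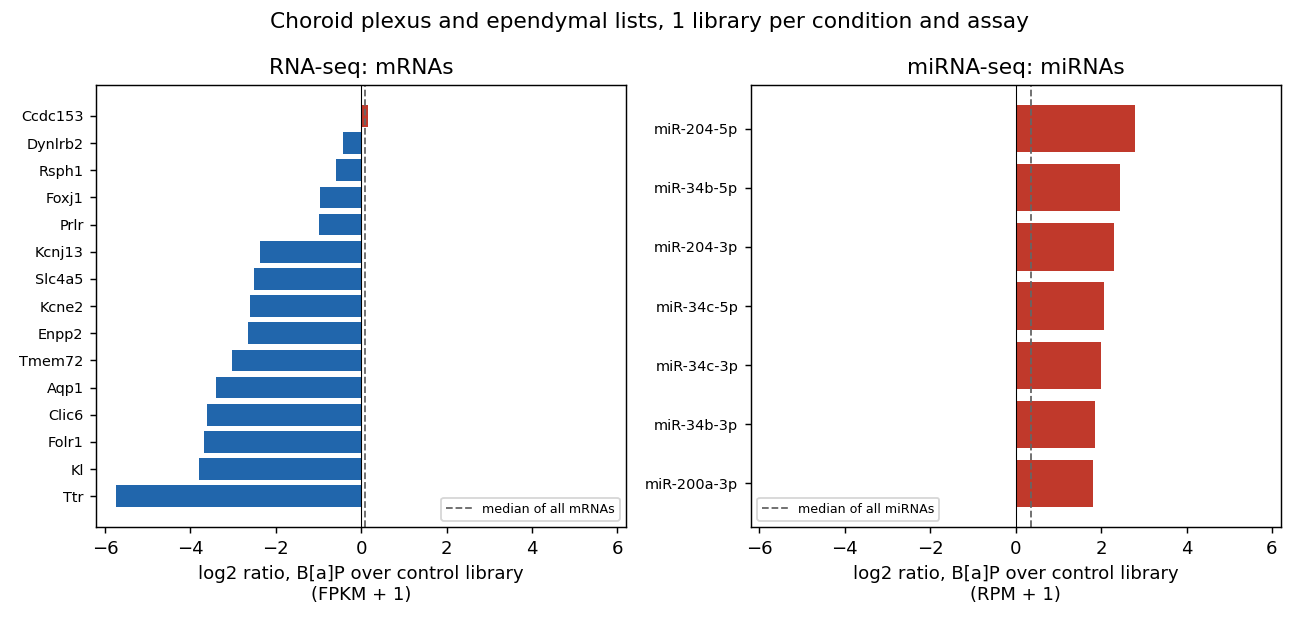
Log2 ratio, B[a]P over control library, of each choroid plexus and ependymal mRNA (left, FPKM + 1) and miRNA (right, RPM + 1) above the floor, 1 bar per gene or miRNA arm. The dashed line is the median of each table, and the lists' medians were -2.60 and 2.06.

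The RRBS libraries were compared for the level of CpG methylation and for single sites and regions that differed. Over the 1215420 CpG sites present in both at 10 or more reads, 20.2% of reads were methylated in the B[a]P library (Wilson 95% interval 20.2 to 20.3) and 17.2% in the control library (17.2 to 17.2), a difference of 3.05 percentage points. This difference depended on how sites were weighted. The mean of the sites' levels was 25.97% and 25.67%, a difference of 0.302 points, and weights common to both libraries, chosen after seeing the data, gave 18.7% and 18.7%, a difference of 0.0232 points. Levels per site were bimodal, with 64.4% of sites under 10% and 13.4% at 90% or more in the B[a]P library, against 64.6% and 13.2% in the control library. By the mean of sites, all 21 nuclear chromosomes measured were higher in the B[a]P library, from 0.0194 points on chromosome X to 0.493 points on chromosome 20. The 449 mitochondrial CpG sites had 1.51% methylated reads in the B[a]P library and 1.86% in the control library, and cytosines outside CpG had 0.662% and 0.680% in the CHH context.

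Single sites differed in both directions. A site is a single cytosine, so the strands of a CpG count separately here, in the clusters and in the tiles. Fisher's exact test on the reads, which compares these libraries and not the conditions, called 840 sites higher and 953 lower in the B[a]P library at an adjusted p under 0.05 and 25 percentage points or more. These were 0.148% of the sites tested, and 91.5% of sites differed by less than 10 points. At 191 CpGs both strands were called, so the called sites are more than the distinct CpGs they lie in. The largest cluster lay on chromosome 1 from 13500000 to 13509999 (rn5), where 168 of 598 sites were lower and 0 higher. Without it the split turned, to 840 sites higher and 785 lower. Methylated reads there were 11.2% in the B[a]P library and 23.0% in the control library. Coverage there was uneven, at a median of 105 reads (B[a]P) and 293 reads (control), against 57 and 74 over all tested sites. The reason was not tested, so this cluster need not be a change of methylation at 1 locus. The next, on chromosome 14 from 47850000 to 47859999, had 39 of 47 sites higher and 0 lower (45.5% against 8.03%). Clusters on chromosome 1 from 151960000 to 151979999 had 25 and 26 sites lower in adjoining 10 kb windows.

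Of the 3 most significant higher sites, 2 were close to all or nothing. On chromosome 10 at 6849204, 213 of 217 reads were methylated in the B[a]P library (98.2%, Wilson interval 95.4 to 99.3) and 0 of 221 in the control library (Wilson interval 0 to 1.71), with a Fisher's exact adjusted p = 6.43e-119. On chromosome 5 at 171990885 the counts were 261 of 281 reads (92.9%) against 0 of 248 (Fisher's exact adjusted p = 5.87e-124), and on chromosome 3 at 175164193 they were 206 of 258 (79.8%) against 2 of 304 (0.658%). The 3 most significant lower sites all lay in the chromosome 1 cluster and were deep: at 13503710, 382 of 1825 reads (20.9%) against 5315 of 7452 (71.3%), at 13505872, 19.3% against 56.3%, and at 13505858, 17.1% against 53.1%. At 90 points or more, 86 sites were higher and 67 lower, more than the 61 sites that differed by 80 to 90 points.

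**Figure D3:**
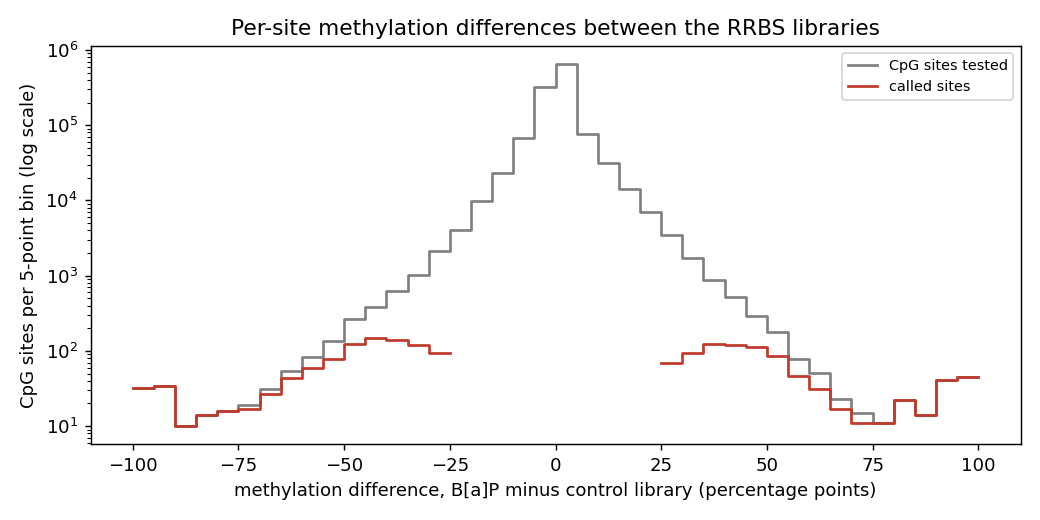
Number of CpG sites (y axis, log scale) in bins of 5 percentage points of the methylation difference, B[a]P minus control library (x axis). The grey line is all 1215420 sites tested and the red line the called sites, which increase again at the ends, beyond 90 points.

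Regions were compared as 1 kb tiles on the files' coordinates, since no gene annotation of that build was used here, so no gene can be named for them. Of 49224 tiles with 5 or more shared sites, 1086 were higher and 461 lower in the B[a]P library by 10 points or more at a Fisher's exact adjusted p under 0.05. Of these 1547 tiles, 1064 also differed by 10 points or more the same way in the mean of their sites. The highest was on chromosome 7 from 88816000 to 88816999, with 62.6% against 17.1% over 10 sites. Next came chromosome 14 from 47849000 to 47849999 (52.6% against 8.03%, 9 sites), beside the cluster above, and chromosome 14 from 18758000 to 18758999 (75.7% against 34.6%, 5 sites). Those on chromosome 5 from 161026000 to 161026999 (56.0% against 15.6%), chromosome 20 from 12284000 to 12284999 (88.4% against 49.3%) and chromosome 10 from 76209000 to 76209999 (63.9% against 25%) had 6 sites each. The lowest was on chromosome 19 from 5827000 to 5827999, with 11.9% against 77.1% over 6 sites. Then followed chromosome 1 from 220655000 to 220655999 (8.73% against 54.5%), chromosome 1 from 52560000 to 52560999 (43.2% against 87.1%), chromosome 14 from 46742000 to 46742999 (23.8% against 65.3%), and chromosome 1 from 13506000 to 13506999 (18.5% against 59.1%, 35 sites) and from 13503000 to 13503999 (16.3% against 55.3%, 111 sites). The chromosome 1 tiles from 13503000 and from 13506000 lie in the cluster above, where the control library was much deeper. Reads of neighbouring sites are not independent, so the adjusted p of a tile is too small.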

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

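Weighting by the lower coverage of each site was the only alternative chosen after the data were seen. Of 52 recomputed counts and levels, 34 stayed within 1.5 times the reported count and 18 did not or, for the methylation level, moved by more than counting error. Among mRNAs, a pseudocount of 0.1 gave 53 higher and 127 lower genes, and a floor of 5 FPKM 11 and 36. Scaling to the median (18 and 75) or the upper quartile (17 and 76) changed these counts less. Dropping the floor left 20 and 69 by construction: with a pseudocount of 1, a gene under 1 FPKM in both libraries cannot reach 2-fold. Both of these counts are among the 34. Without a floor, 57 lncRNA lines were higher and 41 lower, and 26 miRNAs were higher. Scaling to the median took the share of lncRNA lines past the size rule that were higher from 53.8% to 42.4%. Under the median of ratios or without the 3 most abundant miRNAs, 11 miRNAs in place of 13 were at least 2-fold higher. The number of miRNAs at least 2-fold lower was 1 in place of 0 under the median of ratios, without the 3 most abundant miRNAs, with a pseudocount of 0.1 and without a floor. The CpG methylation difference was 2.65 points at 20 reads, 3.31 points without the deepest 0.1% of sites, 0.302 points as a mean of sites and 0.0232 points with common weights. The last alternative differs only in using the same weights for both libraries, so most of the read-weighted difference came from where each library's reads fell. Requiring 50 points left 323 sites higher and 336 lower, by construction fewer, and 20 reads left 289 tiles lower, out of 39694 tested.

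Of 144 recomputed list medians, 112 moved by less than 0.5 of the width of the central 95% of random lists, 27 moved further, and 5 of lists outside their random range changed sign. The glucocorticoid-responsive list was at -0.0422 with scaling to the median and -0.0337 as a mean, cytosolic ribosomal proteins at -0.0150 and -0.0167, and neuronal miRNAs at -0.11 under the median of ratios. Among lists inside their random range, the sign also changed for monoamine and acetylcholine receptors (-0.0259 with scaling to the median, counted among the 112) and, under the median of ratios, for let-7 (-0.00853), blood-enriched (-0.0961) and inflammation-associated miRNAs (-0.0619), counted among the 27. These lists lay near 0 or near their table's shift, and the cause was not tested further for the means. The numbers of lists above and below random lists (14 and 12) were the same with a smaller pseudocount, and 12 and 8 for means. Scaling left 14 and 12 too, by construction, since it shifts a list and its random lists nearly alike. For the same reason, whether a rescaled list counted among the 112 or the 27 depended mainly on the width of its random range. A coverage minimum of 5 reads was not run because every deposited site had 10 or more. The promoter windows and the comparison of promoters with expression were not run, for want of an annotation. No paired analysis was possible because each group has 1 library. Bias by transcript length or GC content was not tested, so shifts of 0.1 to 0.3 in list medians remain open to it. Whether the cell type and functional lists shifted together through different amounts of tissue in the dissected samples was not tested either.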

Other observations

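Only the test on neighbouring CpG sites and the ratio of calls between strands were set before their results were seen, and the tests on the choroid plexus, on p53 and the source of miR-34b and miR-34c, on matching between strands and on treatment against animals were chosen afterwards. The ratio between strands met the bound written for noise of a library. Recurrence of strand differences in both libraries, and the reason given below for leaving that noise open, were looked at only after that. The test of neighbouring tissue replaced an earlier version, on the share of choroid plexus markers, after values were known. Its pineal list was written after Tph1 was seen but before the values of the listed genes were, and its bounds after them.

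Some differences outside the lists were picked out after their values were seen. The class I major histocompatibility genes RT1-A2 (0.314 against 6.05 FPKM), RT1-CE5 (0.716 against 3.93 FPKM) and RT1-N2 (0.291 against 2.11 FPKM) were lower in the B[a]P library while RT1-M6-2 was higher, in a family that varies between individual rats and shares reads. LOC100362027 was at 147.6 against 0.308 FPKM, opposite to Rpl30. Of the 22 tRNA symbols above the floor, which are those of the mitochondrial tRNA genes, 7 were at least 1.5-fold higher and 0 lower, among them Trna (1777 against 1053 FPKM) and Trnc (1154 against 669 FPKM). The pituitary hormone genes Pomc (1.92 against 7.50 FPKM) and Gh1 (2.48 against 4.95 FPKM), the epithelial keratin genes Krt8 (1.16 against 3.39 FPKM) and Krt18 (0.625 against 2.34 FPKM) and the collagen gene Col8a1 (0.304 against 3.01 FPKM) were lower.

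Choroid plexus transcripts pointed opposite ways in the RNA assays, lower among mRNAs (median log2 ratio -2.60) and higher among miRNAs. The choroid plexus miRNA list lay 1.70 above the median of all miRNAs. If the libraries carry the right labels, this argues against less choroid plexus tissue in treated animals as the cause of both. That holds only as far as the listed miRNAs come from choroid plexus. The list's median was that of miR-34c-5p, and the source of its miR-34b and miR-34c arms is left open below. The list's miR-204 arms lay 2.42 and 1.95 above the median of all miRNAs. Different amounts of neighbouring tissue in separately dissected samples remain a candidate explanation: 11 of 13 genes of the pineal gland, which lies near the choroid plexus, were higher in the B[a]P RNA-seq library, against 56.2% of genes of like level. That support is weak, since all 11 lie below 1 FPKM, such as Sag (0.203 against 0.0123 FPKM), Rom1, the only listed gene above it (3.62 against 4.08 FPKM), and the melatonin synthesis gene Aanat (0.0386 against 0.0546 FPKM) were lower, and the list of neighbouring region markers fixed in advance (thalamus, habenula, striatum and cortex) lay inside its random range (median 0.05, percentile 27.1) with 0 of 16 genes at 1.5-fold. Exchanged labels in 1 assay cannot be told apart from this, because no measure identified an animal in both assays: an exchange turns the miRNA value to -1.70 by construction, which tests nothing, and relative to random lists the oligodendrocyte lists (mRNA median -0.13, percentile 0, and miRNA median 0.56, percentile 99.3) and the neuronal lists (mRNA percentile 97.9 and miRNA percentile 0.065) also lay on opposite sides. Other pairs were less clear, since their miRNA lists lay inside the random range. The blood lists both lay low (mRNA percentile 0.15 and miRNA percentile 25.3), and the endothelial lists lay apart (mRNA percentile 0.02 and miRNA percentile 85.0). A change of choroid plexus expression by B[a]P in 1 assay's animals stays open and untested.

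The higher miR-34b and miR-34c in the B[a]P library might come from p53, which DNA damage activates and which induces the miR-34 family. The other 8 p53-associated miRNAs, miR-34a-5p among them, had a median only 0.0917 above that of all miRNAs. This argues against p53 across the tissue as the whole explanation. In the RNA-seq libraries, the p53 target mRNAs lay below their table's median by -0.09. That value adds to the argument only if the libraries of both assays carry the right labels. Whether the assays used the same animals is also not stated. Choroid plexus or ependymal RNA in that sample as the source cannot be told apart from other sources. miR-204-5p, miR-448-3p and miR-1298 lay 2.42 or more above the median. This set was picked from the largest ratios of the table, so its test had a fixed outcome. Of the set, miR-204-5p was also in the choroid plexus list fixed in advance. In that list, miR-204-3p and miR-200a-3p lay 1.95 and 1.44 above the median, but reached the floor in the B[a]P library only. These values do not show where miR-34b and miR-34c came from. The 4 miR-34b and miR-34c arms are in both fixed lists, so the lists are not independent.

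The CpG sites that differed between the RRBS libraries may in part be sequence variants of the animals, which read as lost methylation where a C is replaced by T. Of 1719 called sites with another shared CpG 2 to 50 bp away, 58.4% had that neighbour differing by under 10 points, but so did 92.4% of all sites, so this does not separate a variant from other differences of a single site, and 36.8% had it differing the same way by 10 points or more, which a variant at the site alone would not give. Of 398 calls on the upper strand, 84.2% were matched by a difference of at least 10 points the same way on the other strand. This argues against noise arising separately in each strand's reads as the source of most of these calls. By the full rule for calling a site, 191 CpGs were called on both strands. Other noise of a library cannot be told apart: calls between strands within a library were 1.47 times as many as calls between libraries, 63.7% of those in the B[a]P library and 46.8% of those in the control library were found in both, and calls found in 1 library only were still 0.675 times as many, which the matching between strands opposes. With 1 library per condition, the treatment cannot be told apart from a difference between animals.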
